A study of Mus musculus with 8 samples.

How the data were processed

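Gene expression was measured in AML12 cells, a mouse hepatocyte line, and in AML12 cells transfected with v-erbA. v-erbA is the oncoprotein of avian erythroblastosis virus, a mutated thyroid hormone receptor that represses target genes. Each line was left untreated or given 1 µM retinoic acid (RA) and was sampled at 3 h or 24 h, per the labels. The 8 combinations were covered by 8 arrays, 1 array per combination, so that no combination was replicated. Line, treatment and time were taken from the sample titles. For 3 of the 4 samples titled 24 h the description names 3 h, and the titles were followed. Total RNA was isolated with Trizol and a column kit and labelled with biotin for Affymetrix arrays, per the labels' protocols.

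The deposited table holds 1 signal intensity per probe set and array on a linear scale, from 0 to 12275 units. The summarization of probes and the scaling between arrays that the authors used are not given in the sources used here. The medians of the 8 arrays lay between 71.2 and 76.1 units, and the deposited scaling was kept. The table lists 45037 probe sets, of which 1 had no value on the 4 arrays of 24 h and was left out. It holds 0 control probe sets of the manufacturer, so the check of RNA integrity by 3' to 5' ratios could not be run. No detection calls or background values were used, and the number of arrays limits the precision.

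Probe sets were named through the platform annotation. Of them 34944 named 1 gene, 932 named several genes and 9160 named none; the last 2 kinds were not used. Gene identifiers of 34740 probe sets were found in the RefSeq gene table of the mouse assembly GRCm38.p6 and 204 were not. The update through that table changed 0 symbols. The named probe sets covered 18192 genes, 9010 of them with more than 1 probe set, and the probe set with the highest mean over the 8 arrays stood for the gene.

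Values were transformed to log2(signal + 19.9), where the offset is the 20th percentile of all values pooled. Differences on this scale understate the change of dim genes. A gene was tested if at least 2 of the 8 arrays exceeded the pooled median of 73.5 units; this left 11997 genes and removed 6195 as dim. Where all arrays of the lower group lay under that median, the fold is given as a bound, the mean of the higher group against the median level, for the genes named from a test, and no fold is given where that mean too lies under the level. Ratios of single arrays follow the same rule. Differences of RA responses are given as measured, with the value for dim signals set to the level beside them where untreated arrays were dim. Fits used limma 3.58.1 in R 4.3.3 with a mean-variance trend in the empirical Bayes step and Benjamini-Hochberg adjustment, and the threshold was an adjusted p under 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

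The effects of v-erbA, RA and time came from an additive model of line, treatment and time over all 8 arrays with 4 residual degrees of freedom. RA effects within each line and their difference came from a model with a line by treatment term, and the difference between times from a model with a treatment by time term, each with 3 residual degrees of freedom. The spread in these models is the departure of the arrays from additivity. For pairs of single arrays no test was made, and genes with a ratio of at least 2-fold were counted where 1 of the 2 arrays exceeded the pooled median.

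The genes named in the text were chosen by a rule fixed before the data were examined. For the v-erbA effect it takes the 12 highest and 12 lowest changes among genes past the threshold with the same direction in all 4 matched pairs. For RA over both lines it takes 10 and 10, for RA in each line 8 and 8 with the same direction at both times, for each difference of RA effects 8 and 8, and for time 5 and 5. Where fewer passed, all were taken, and where none passed, the 5 with the smallest p. For single pairs of arrays it takes the 5 largest rises and 5 largest falls. Always included were Cyp26a1, Rarb, Dhrs3, Stra6, Crabp2, Tgm2, Thra, Thrb, Rxra, Ncor1, Alb and Afp, and 2 to 4 examples per gene list. Of these Ncor1 was not analysed here, and other genes of the rule are not reported here.

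In addition 21 gene lists with 429 members were fixed before the data were examined, 2 of the members being matched through an older symbol. They hold retinoic acid targets and retinoid handling, thyroid hormone responsive genes, nuclear receptors and coregulators, hepatocyte, biliary and progenitor, mesenchymal and fibroblast, macrophage and endothelial markers, and epithelial junction genes. The others hold cell cycle, cholesterol synthesis, fatty acid synthesis, interferon-stimulated, inflammatory and acute phase, immediate early, ER stress and amino acid response, hypoxia and glycolysis, and xenobiotic and antioxidant genes, Wnt targets, TGF-beta and matrix genes, and p53 targets and apoptosis genes. Each list was tested with limma's camera with a preset correlation of 0.01 and with an estimated correlation, two-sided, adjusted over the 21 lists. In single pairs of arrays the median of a list was ranked among 10000 random lists of the same size matched on mean expression. The RA response of the called genes was compared between lines with limma's fry, a rotation test of whether a set moves on balance in one direction, and likewise between times, for all called genes and for those called higher or lower. Its p-values were adjusted over these 6 tests.

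Scaling, offset, dim filter, choice of probe set, the trend, all 2-way interactions, matched pairs as a block and the omission of each array in turn were tried as alternatives, and their effects are given with the additional observations. The procedure was tested on simulated data in 10 runs with 200 changed genes among the 11997. Of simulated changes of 2-fold it recovered 95.2% for the v-erbA effect, 96.0% for RA over both lines, 84.6% for RA in AML12, 84.8% for RA in the v-erbA line, 66.2% for the difference of RA effects between lines and 66.4% for that between times. False calls averaged between 6.4 and 10.0 per run. A simulated list shifted by 0.5 log2 units had an unadjusted camera p under 0.05 in 10 of the 10 runs and an unshifted list in 2 of them. Genes were simulated as independent of each other, with noise independent between arrays, so the recovery may differ in the real arrays. In the additive fit to the real arrays the estimated correlation was 0.69 for cell cycle genes and 0.40 for hepatocyte markers. The simulation therefore does not check the preset correlation of 0.01.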

Results

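Transcript levels in mouse AML12 hepatocytes and in AML12 cells carrying v-erbA were compared on 8 oligonucleotide arrays. The lines were left untreated or exposed to 1 µM retinoic acid (RA) for 3 h or 24 h, and each of the 8 combinations was represented by 1 array. Median signals ranged from 71.2 to 76.1 units. Over the 11997 genes tested, Pearson's correlation across genes was 0.985 to 0.996 between arrays that differed only in treatment, 0.950 to 0.966 between those that differed only in line and 0.934 to 0.946 between those that differed only in time. Time accounted for 53.1% of the variance between arrays, line for 36.0% and treatment for 3.33%. The share of time includes changes of at least 2-fold that a second probe set seldom followed (18 of 94 genes). It therefore cannot be read as change of expression alone. No combination was replicated, so the p-values measure only the spread among these arrays, which may be sister cultures of 1 transfected line. The effect of v-erbA cannot be separated from that of transfection and clone. Changes are log2 differences ± SE of the limma fit.

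The first comparison asked which genes differed with v-erbA, over 4 pairs of arrays matched by treatment and time. The v-erbA transcript itself was not analysed here, so its level in the transfected line was not checked. Liver proteins stood among the largest decreases. Apoa1, the main protein of high-density lipoprotein, fell by 2.98 ± 0.31, Adh1, an alcohol dehydrogenase, fell by 3.09 ± 0.23, and the secreted plasma protein Lrg1 fell by 3.63 ± 0.18. Pilrb1 fell by 4.63 ± 0.08, the cationic amino acid transporter Slc7a2 fell by 4.13 ± 0.13, the kynurenine aminotransferase Kyat3 fell by 3.81 ± 0.07 and Tmem45a fell by 2.86 ± 0.30. Klhl13, Igf2r, Cyp4b1, Crtap and Hpn, the last a hepatocyte serine protease, lay below the pooled median on all 4 v-erbA arrays and were at least 11.4-fold, 7.02-fold, 5.27-fold, 3.81-fold and 3.65-fold lower there. Among genes that were higher with v-erbA, Bche, which encodes butyrylcholinesterase, rose by 3.42 ± 0.09, the protease Prss23 by 2.86 ± 0.11, Armcx3 by 2.73 ± 0.07, the ankyrin repeat gene Ankrd1 by 2.72 ± 0.10 and the glutaminyl cyclase Qpct by 2.71 ± 0.11. Ptprm, Ajap1, Hoxb13, Ceacam10, Rasl10b, Flt1 and Elavl2 lay below the median on all 4 control arrays and were at least 4.33-fold, 3.81-fold, 2.91-fold, 2.57-fold, 2.48-fold, 1.80-fold and 1.67-fold higher. By the rule that chose them, all these genes had the same direction in 4 of 4 pairs and passed the threshold (limma adjusted p of at most 7.81e-05). Of the 15 other probe sets of these genes 14 pointed the same way by sign, some with far smaller changes. Those of Slc7a2 differed by -3.23, -0.81 and 0.02, and that of Elavl2 by 0.73.

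Hepatocyte markers were mostly lower with v-erbA. Of 25 measured, 18 fell, 2 rose and 5 did not pass, also when adjusted over the list alone. Apoh (-1.95), the fibrinogen gene Fgg (-1.82) and the liver transcription factors Cebpa (-1.05) and Hnf4a (-0.63) fell. Serpina1b, an antitrypsin gene, rose by 1.89 and the forkhead factor Foxa3 by 0.59, and Alb, which encodes albumin, differed by -0.07 ± 0.04 (limma adjusted p = 0.101). The median of the list was -0.66 (camera adjusted p = 1.06e-04), and -0.24 over 12 other probe sets of its members. The call was lost with an estimated correlation (adjusted p = 0.476 with an estimated correlation).

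Lipid synthesis genes were also lower. In cholesterol synthesis 16 of 17 genes fell and 0 rose, the same counts as adjusted over the list alone, with a median of -0.72 (limma camera adjusted p = 1.90e-07; adjusted p = 0.316 with an estimated correlation) and of -0.46 over 15 other probe sets. Insig1, a sterol sensor (-1.32), the squalene synthase Fdft1 (-1.16), Cyp51 (-0.99) and the isomerase Idi1 (-0.90) were among those that fell. In fatty acid synthesis 11 of 15 fell, 12 when adjusted over the list alone, and 0 rose, with a median of -0.39 (camera adjusted p = 1.91e-04; adjusted p = 0.209 with an estimated correlation). The desaturase Scd1 (-1.75), the carbohydrate-responsive factor Mlxipl (-1.47) and the sterol-regulated factor Srebf1 (-0.42) fell.

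Stress, hypoxia and detoxification lists were shifted downwards. Of 18 genes of ER stress and amino acid response 12 fell and 2 rose (13 and 3 adjusted over the list alone), among them the chaperone Hspa5 at -0.56, the transcription factor Ddit3 at -0.78, Trib3 at -1.32 and Sdf2l1 at -1.56. The median was -0.40 (limma camera adjusted p = 0.00104; adjusted p = 0.330 with an estimated correlation), and -0.11 over 23 other probe sets, 22 of which pointed the same way as the used ones. Of 18 hypoxia and glycolysis genes 11 fell and 2 rose (13 and 2 adjusted over the list alone), with a median of -0.41 (camera adjusted p = 0.00336; adjusted p = 0.463 with an estimated correlation). The glucose transporter Slc2a1 (-1.02), the kinase Pdk1 (-0.97) and the growth factor Vegfa (-0.61) fell. Of 17 xenobiotic and antioxidant genes 11 fell and 3 rose, the same counts as adjusted over the list alone, with Cyp3a11 at -1.75, Tiparp at 0.86 and the glutathione transferase Gsta2 at least 3.04-fold lower. That list had a median of -0.40 (camera adjusted p = 0.00209; adjusted p = 0.209 with an estimated correlation).

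The other lists did not pass camera for v-erbA (limma camera adjusted p from 0.0701 to 0.984), and single members differed in both directions. Median and mean differed in sign for retinoid genes (-0.02 and 0.05), nuclear receptors (0.04 and -0.07), mesenchymal markers (0.01 and -0.13) and TGF-beta genes (-0.04 and 0.02, camera direction down). Of 20 interferon-stimulated genes 11 fell and 3 rose (camera adjusted p = 0.0701), with the proteasome subunit Psmb8 at -1.50, Oasl2 at least 1.09-fold lower, the chemokine Cxcl10 at 1.13 and Ifit2 at 1.25. Of 16 immediate early genes 10 rose and 5 fell (camera adjusted p = 0.105), with Fos at least 1.30-fold higher, Atf3 at 1.47, Ccn1 at 1.23 and Fosl1 at -2.26. Of 16 inflammatory and acute phase genes 7 rose and 6 fell, with the chemokines Ccl20 at 1.77 and Ccl7 at 1.41. Among 21 nuclear receptors and coregulators 5 rose and 5 fell: Nr0b2 fell by 2.07 and the retinoid X receptor Rxra fell by 0.91 ± 0.07, while Pparg rose by 1.05, the coactivator Ncoa1 by 0.84 and Thra, the thyroid hormone receptor gene from which v-erbA derives, by 0.41 ± 0.06. Thrb lay below the dim filter. Among 13 thyroid hormone responsive genes 3 rose and 5 fell, with Gpd2 at -0.70 and Me1 at -0.58, and among 14 retinoid genes 3 rose and 2 fell, with Meis1 at 1.27 and Rai14 at -0.79.

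Cell cycle genes gave 7 higher and 1 lower of 28 (6 and 1 adjusted over the list alone), with Ccnb2 at 0.69 and Tk1 at -0.45. Without the untreated 24 h AML12 array these were 6 higher and 5 lower, and the median of the list was 0.00 in place of 0.18. Epithelial junction genes gave 4 higher and 6 lower of 14, with Cldn2 at -1.54 and Gjb1 at -1.14, and mesenchymal and fibroblast markers 3 higher and 4 lower of 12, with Acta2 at 0.68 and Postn at -0.96. Biliary and progenitor markers gave 2 higher and 2 lower of 9, with Afp, which encodes alpha-fetoprotein, at 0.75 ± 0.09 and Krt19 at -0.93. Macrophage markers gave 0 higher and 1 lower of 4 (Cd14, -0.91), and endothelial markers 1 higher, Flt1, and 0 lower of 4, the mean (0.58) and the median (-0.09) differing in sign. Wnt targets gave 1 higher and 5 lower of 7, with Glul at -0.97, TGF-beta and matrix genes 3 higher and 4 lower of 14 (6 lower adjusted over the list alone), with Tgfb2 at 2.03, and p53 targets and apoptosis genes 3 higher and 6 lower of 15 (7 lower adjusted over the list alone), with Perp at -0.87. Among all genes tested with limma, 3177 were higher and 3236 lower with v-erbA, 53.5% of those tested, and 406 changed at least 2-fold (156 higher, 250 lower). The direction was the same in all 4 pairs for 6268 of the 6413. No single array moved this count by over 1.5 times. With each array centred on its median the split was 2741 higher and 3576 lower, and with quantile normalization 3496 higher and 3089 lower. The balance of directions therefore depends on the scaling.

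The second comparison asked which genes responded to RA, averaged over lines and times. Nr0b2, an orphan receptor that represses bile acid synthesis, rose by 2.10 ± 0.17 and Nrip1, a corepressor known as a target of retinoic acid receptors, rose by 1.67 ± 0.12 (limma adjusted p = 0.00125 for both, higher in 4 of 4 pairs). Of the cornified envelope genes, Ivl rose by 1.17 ± 0.12 and Sprr1a rose from a mean log2 level of 7.96 without RA to 9.96 with RA (SE of the difference 0.32). The flavin monooxygenase Fmo5 and Wfdc3 each rose by 1.22, the orphan receptor Gprc5b by 1.12, Flrt3 by 1.03, the bile acid transporter subunit Slc51b by 0.95 and Epn2 by 0.89. Of the genes that decreased, the prostaglandin-degrading enzyme Hpgd fell by 1.13 ± 0.16, the glycogen-targeting phosphatase subunit Ppp1r3c fell by 1.06 ± 0.18 and Ppara, a nuclear receptor of fatty acid oxidation, fell by 0.93 ± 0.11. Rgs2 (-0.65), AA986860 (-0.62), Sema6d (-0.57), Tox (-0.55), Ccn4 (-0.54), Plpp3 (-0.53) and Zbtb16 (-0.52) also fell. By the rule that chose them, each of these genes had the same direction in 4 of 4 pairs and passed the threshold (limma adjusted p of at most 0.0481). All 24 other probe sets of these genes pointed the same way by sign, some with far smaller changes. Those of Nrip1 differed by 0.05, 0.13, 1.07, 1.58 and 1.66.

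**Figure D1:**
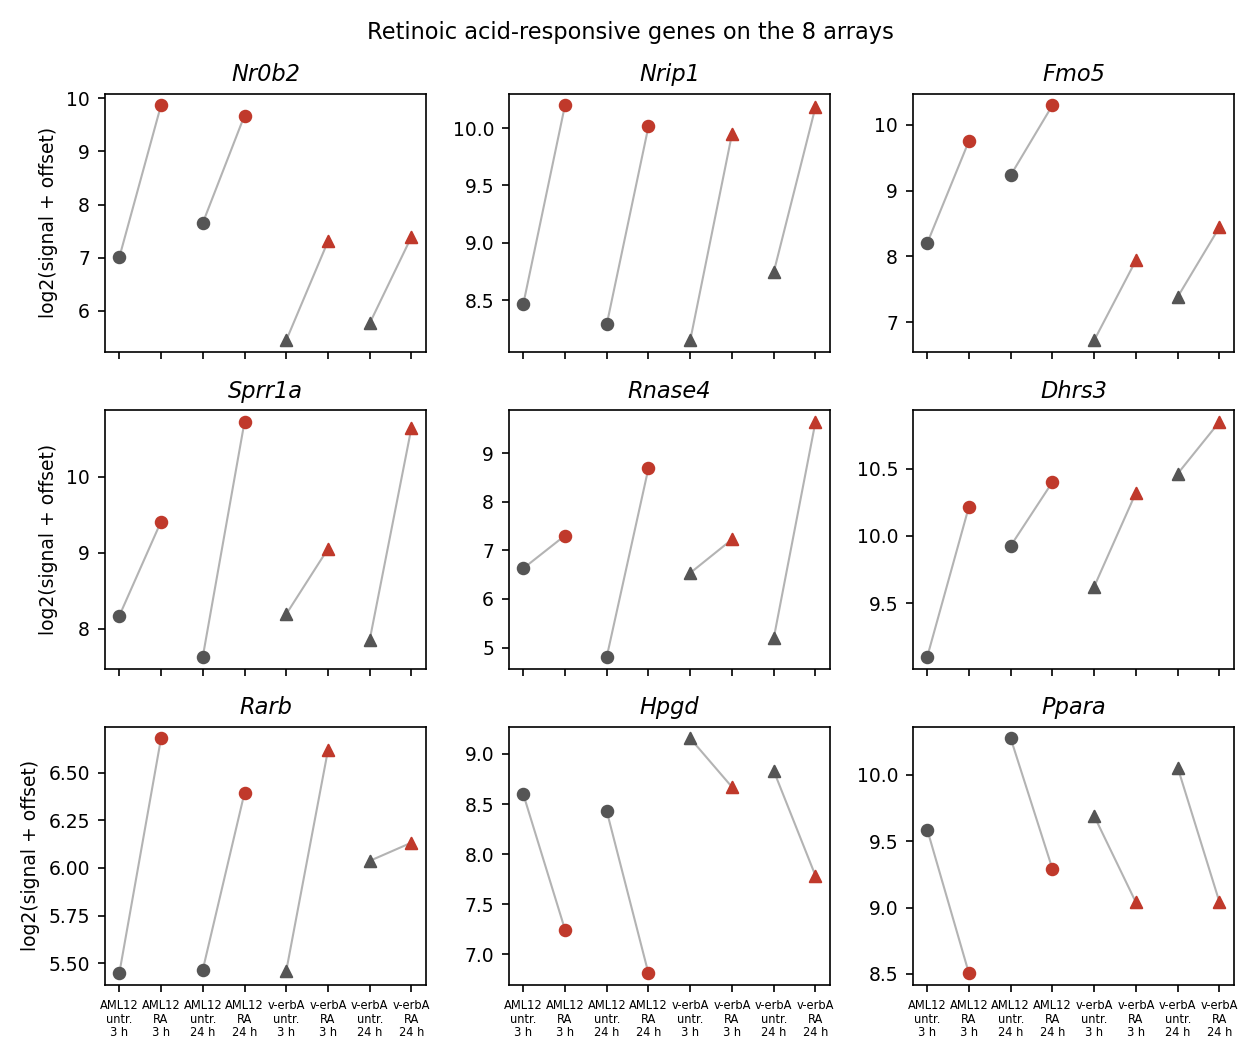
Log2(signal + offset) of 9 genes on each of the 8 arrays, with AML12 as circles, v-erbA AML12 as triangles, untreated arrays in grey and RA arrays in red; lines join the arrays of a line and time, and the vertical axes differ in range. With RA at 3 h Nr0b2 was at 9.87 in AML12 and at 7.31 in the v-erbA line, each above its untreated array.

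Of 14 retinoid genes 3 rose with RA and 0 fell (6 rose adjusted over the list alone). They were Nrip1, Dhrs3, which encodes a retinaldehyde reductase, at 0.67 ± 0.10 (adjusted p = 0.0196), and the retinol dehydrogenase Rdh10 at 0.42. The list had a median of 0.20 (limma camera adjusted p = 5.58e-06; adjusted p = 0.202 with an estimated correlation). Other retinoid genes included by rule did not pass. The receptor gene Rarb (limma adjusted p = 0.0790) lay below the pooled median on all 4 untreated arrays and in its mean with RA, so no fold is given. Cyp26a1, an RA-degrading enzyme, and Crabp2 also lay below it in the means with and without RA. For Crabp2 this came from averaging over times, since it lay above that level on all 4 arrays of 3 h and below it on all 4 of 24 h. With RA it differed by 0.22 ± 0.13 (limma adjusted p = 0.619). Tgm2 differed by 0.18 ± 0.05, and Stra6 lay below the dim filter.

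Outside the retinoid list, single members of other lists passed. Sox9 rose by 0.55, Bcl2 by 0.58, Abcc2 by 0.38, Id3 by 0.36, Cd14 by 0.33 and Ccn1 by 0.28, while Vldlr (-0.45), Cebpd (-0.44), Pmaip1 (-0.36) and Hnf4a (-0.27) fell. Hepatocyte markers had 0 higher and 1 lower of 25, also adjusted over the list alone, and a median of -0.12 (limma camera adjusted p = 8.12e-05; adjusted p = 0.594 with an estimated correlation). The same list without the untreated 24 h AML12 array gave a median of -0.04 (camera adjusted p = 0.126). Cell cycle genes had 0 of 28 past the threshold, also adjusted over the list alone, and a median of 0.22 (camera adjusted p = 5.03e-07; adjusted p = 0.594 with an estimated correlation), 0.08 without that array (camera adjusted p = 0.00118). Fatty acid synthesis genes had 0 of 15 past the threshold, 3 higher adjusted over the list alone, and a median of 0.06 (camera adjusted p = 0.0305; adjusted p = 0.443 with an estimated correlation). Among all genes tested with limma, 99 were higher and 44 lower with RA, all 143 with the same direction in 4 of 4 pairs, and 10 changed at least 2-fold (8 higher, 2 lower).

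With each array centred on its median the split for RA was 140 higher and 31 lower, so 81.9% in place of 69.2% of the called genes were higher. Without the mean-variance trend 17 genes passed (17 higher, 0 lower), and with all 2-way interactions in the model 628. Leaving out the untreated AML12 array gave 57 genes at 3 h, and leaving out the AML12 RA array gave 36 at 3 h and 87 at 24 h. Leaving out the untreated v-erbA array gave 78 at 3 h and 63 at 24 h, and leaving out the v-erbA RA array at 24 h gave 48.

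The comparison that the design names is the RA response in the presence of v-erbA. In AML12 alone, over both times, Nr0b2 rose by 2.45 ± 0.18, Nrip1 by 1.73 ± 0.17, Fmo5 by 1.31 ± 0.13, Ivl by 1.24 and Flrt3 by 1.24. Slc51b and the uroplakin gene Upk1a lay below the pooled median on both untreated AML12 arrays and were at least 2.36-fold and 1.16-fold higher with RA; Zfr2 passed but lay below it with RA too. Hpgd fell by 1.49 ± 0.15 and Mgll, which encodes monoacylglycerol lipase, fell by 1.01 ± 0.14. Ccn4 (-0.70), Tox (-0.67), Rnd3 (-0.65), the repressor Zbtb16 (-0.63) and Bambi, a TGF-beta pseudoreceptor (-0.54), fell as well. By the rule that chose them, these AML12 changes had the same direction at both times and passed the threshold (limma adjusted p of at most 0.0468). With v-erbA the smallest limma adjusted p was 0.0525, for Nr0b2 (1.75 ± 0.18, at least 1.75-fold, its untreated arrays lying below the pooled median) and Nrip1 (1.62 ± 0.17), followed by Fmo5 (1.14 ± 0.13), Gprc5b (1.07 ± 0.13) and Epn2 (0.67 ± 0.08), none of which passed. With limma, 29 genes were higher and 7 lower with RA in AML12, 36 in all, and 13 changed at least 2-fold (11 higher, 2 lower). With v-erbA 0 passed with limma, 399 having an unadjusted p under 0.05 against 1089 in AML12. Evenly spread p-values would put a share of 0.05 of the 11997 genes there. The 399 are fewer than that share and by themselves show no response to RA, and the 1089 are more.

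The difference between lines itself was not shown for any gene. The limma interaction test gave 0 genes, 199 with an unadjusted p under 0.05 and a smallest adjusted p of 1.00. The 5 genes with the smallest p were Mgll, with a response higher in the v-erbA line by 1.14 ± 0.20, Tfrc, the transferrin receptor gene (-0.39 ± 0.08), Fv1 (0.81 ± 0.18), Zfr2 and Upk1a. The last pair lay below the pooled median on both untreated AML12 arrays, and their differences as measured, -1.66 and -1.61, were 0.06 and -0.18 with signals below that level set to it. The 199 are fewer than a share of 0.05 of the 11997 genes tested, which evenly spread p-values would give. In simulated data the same test recovered 66.2% of differences of 2-fold, but with noise independent between arrays. In the real arrays line by treatment held 1.37% of the variance. Line by time, treatment by time and the 3-way term, which enter the spread, held 2.58%, 2.03% and 1.51%. The 66.2% may therefore overstate the power here, and the 0 genes do not show equal responses. Leaving out the AML12 RA array at 3 h gave 2 genes for this difference.

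The count of 36 in AML12 depended on single arrays. It was 246 without the untreated AML12 array at 3 h, 8 without that at 24 h, 5 and 8 without the AML12 RA arrays at 3 h and 24 h, and 16 without either untreated v-erbA array. It was 18 with the mean of all probe sets, 2 without the mean-variance trend and 596 with all 2-way interactions. For the v-erbA line, where Nr0b2 and Nrip1 stood just above the threshold, 3 genes passed without either untreated AML12 array and 1 without the untreated v-erbA array at 24 h. There 4 genes passed with median centring or with no dim filter, 3 with a filter that needs all 8 arrays, 1 with no offset and 125 with all 2-way interactions.

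Over the 143 genes called for RA, the mean response signed by direction was 0.578 in AML12 and 0.459 in the v-erbA line, and 115 of the 143 had the smaller response in the v-erbA line. The spread in that call includes differences between lines, so genes that respond in 1 line only are less likely to be called. Mgll, called in AML12 and at 0.13 and 0.14 in the v-erbA line at 3 h and 24 h, is not among the 143. The choice of genes therefore limits the difference between lines that they can show. The difference was -0.143 at 3 h and -0.0957 at 24 h, with a mean of -0.119, and did not pass limma's fry test (adjusted p = 0.332 over the 6 fry tests). It was -0.0656 without the v-erbA RA array at 3 h and -0.0813 without the untreated AML12 array at 24 h. Without the v-erbA RA array at 24 h it was -0.173, the only omission of an array with which the fry test, then unadjusted, passed the threshold. The 99 genes called higher with RA had a mean of 0.611 in AML12 and 0.501 in the v-erbA line, and the 44 called lower had 0.503 and 0.362.

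**Figure D2:**
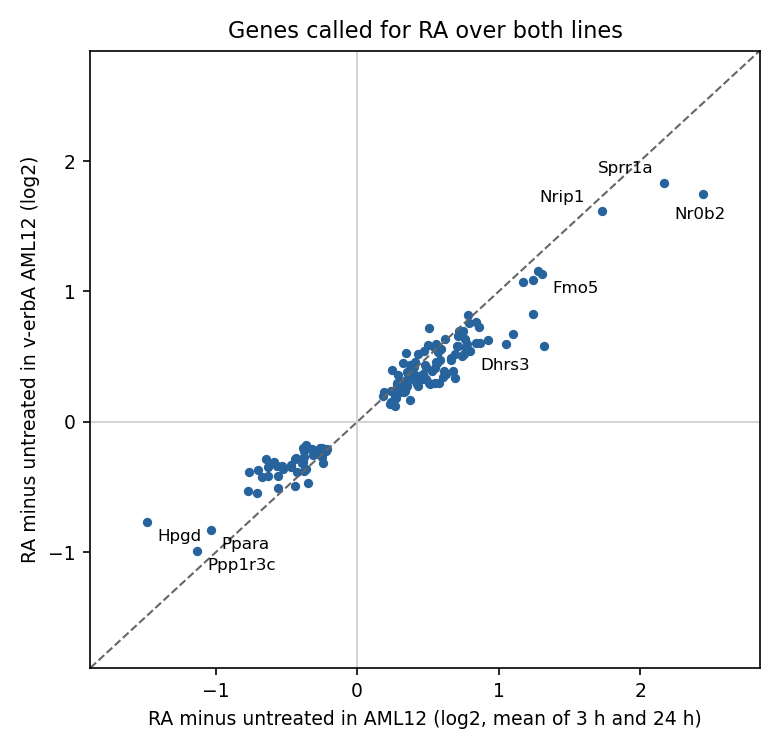
RA minus untreated log2 change in v-erbA AML12 (vertical) against AML12 (horizontal), each the mean of 3 h and 24 h, for the 143 genes called for RA over both lines; the dashed line marks equal responses. As measured, Nr0b2 lies at 2.45 and 1.75 and Hpgd at -1.49 and -0.77. The call over both lines disfavours genes that respond in 1 line only, which partly fixes how close the points lie to the dashed line.

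Retinoid genes had a median RA response of 0.31 in AML12 (limma camera adjusted p = 6.93e-06; adjusted p = 0.290 with an estimated correlation), with 1 past the threshold and 8 adjusted over the list alone. With v-erbA the median was 0.08 (camera adjusted p = 1.23e-04; adjusted p = 0.329 with an estimated correlation), with 0 past the threshold and 3 adjusted over the list alone. The difference between lines did not pass (median -0.10, camera adjusted p = 0.110), and its median was -0.03 without the untreated 24 h AML12 array (camera adjusted p = 0.236). For Dhrs3 the response was 0.79 ± 0.14 in AML12 and 0.54 ± 0.14 in the v-erbA line, neither past the threshold. In the v-erbA line camera also called macrophage markers (median 0.18), cholesterol synthesis (0.08), fatty acid synthesis (0.09) and inflammatory genes (-0.15), with adjusted p of 0.00400, 0.0139, 0.00483 and 0.0123. With an estimated correlation the adjusted p was 0.329, 0.555, 0.329 and 0.555. Cell cycle genes (median 0.07, camera adjusted p = 0.137) passed there without the untreated 24 h AML12 array (camera adjusted p = 0.0334).

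The response to RA was next compared between times. Sprr1a responded more at 24 h than at 3 h by 1.89 ± 0.17, and Rnase4, a secreted ribonuclease, also responded more at 24 h (limma adjusted p = 0.0237 for both, in 2 of 2 lines). These were the 2 genes past the threshold, 912 having an unadjusted p under 0.05. Neither gene had another tested probe set. The 3 h and 24 h arrays may have been handled as separate sets, so a difference in how these probe sets measured at each time is not excluded. Rnase4 lay below the pooled median on both untreated 24 h arrays, so its difference as measured, 3.49, has no firm size. With signals below that level set to it the difference was 1.95 for Rnase4 and 1.89 for Sprr1a, and 0 genes passed (limma adjusted p = 0.443 and 0.130). Rnase4 was at least 4.44-fold higher with RA at 24 h in AML12 and at least 8.58-fold higher in the v-erbA line. Over the 143 genes called for RA the signed mean was 0.490 at 3 h and 0.547 at 24 h (limma fry adjusted p = 0.692 over the 6 fry tests). The spread in that call includes differences between times, so genes that respond at 1 time only are disfavoured, and Rnase4 is not among the 143. With quantile normalization, a double offset or a filter that needs all 8 arrays 1 gene passed for this difference, 0 without the mean-variance trend and 121 with all 2-way interactions. It was 0 genes without the untreated arrays of either line at 3 h or the v-erbA RA array at 3 h, 1 without either AML12 RA array, 17 without the v-erbA RA array at 24 h and 102 without the untreated v-erbA array at 24 h.

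Ratios of single RA and untreated arrays describe the same responses without a test, and a ratio is given as a bound where the lower array lay below the pooled median. At 3 h in AML12, Nr0b2 was at 2.87, Nrip1 at 1.74 and Fmo5 at 1.55, and Mgll at -1.36, Hpgd at -1.35 and Pou2f2 at -1.17. Pou2f2 was at 0.10 in AML12 at 24 h and at 0.04 and -0.09 in the v-erbA line at 3 h and 24 h. Its used probe set differed by -2.77 between times, where its second one differed by 1.32. Upk1a and 2900060N12Rik were at least 1.08-fold and 1.03-fold higher, and Gm16499 and 1110017D15Rik at least 1.45-fold and 1.64-fold lower. At 3 h in the v-erbA line, Nrip1 was at 1.80, Ivl at 1.35 and Fmo5 at 1.21, and Nr0b2 and Rarb were at least 1.70-fold and 1.05-fold higher. There 1700048O20Rik and Myo1f were at least 1.44-fold and 1.39-fold lower, while Pax7, Nt5e and Lipi started just above that level and ended below it, so that no size is given. At least 2-fold higher with RA were 16 genes in AML12 and 6 in the v-erbA line at 3 h, and 8 and 3 were at least 2-fold lower. With dim signals set to the level of the filter these were 11 and 4 higher, and 5 and 0 lower. All 6 higher in the v-erbA line were shared with AML12, against 0.00834 expected for independent lists. Of the genes lower at 3 h, with a ratio in both, 6 were in AML12, 0 in the v-erbA line and 0 shared.

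At 24 h in AML12, Sprr1a was at 3.10, Nr0b2 at 2.02 and Apob at 1.98, and Rnase4 and the kinesin Kifc1 were at least 4.44-fold and 2.37-fold higher. The 5 largest falls there were those of Serpina1c at -2.06, Bhmt at -2.05, the fetuin gene Ahsg at -2.04, Apoa1 at -1.95 and tyrosine aminotransferase (Tat), which was at least 4.21-fold lower. At 24 h in the v-erbA line, Sprr1a was at 2.80 and Wfdc3 at 1.72, and Rnase4, Nr0b2 and Wfdc18 were at least 8.58-fold, 1.80-fold and 1.15-fold higher. Tmem45a was at least 2.46-fold lower, with Ppp1r3c at -1.42, Rexo1 at -1.37, and Ldhd and Serpina7 at -1.09. At least 2-fold higher were 73 genes in AML12 and 13 in the v-erbA line, and 56 and 9 were at least 2-fold lower. The AML12 counts rest on 1 untreated array. Its correlation with the RA array was 0.985, the lowest of the 4 pairs that differed only in treatment. The SD of the log2 ratios was 0.285 in AML12 and 0.182 in the v-erbA line. Whether the larger AML12 counts come from that array or from the line cannot be told with 1 array. Of the genes with a ratio in both, 7 of the 10 higher in the v-erbA line and 5 of the 8 lower were shared with AML12, against 0.0609 and 0.0320 expected for independent lists.

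Hepatocyte markers and cell cycle genes moved in opposite directions with RA at 24 h in AML12. The median ratio was -0.66 for hepatocyte markers and 0.80 for cell cycle genes, at percentiles 0 and 100 of the 10000 matched random lists, as a description of these arrays. In the v-erbA line at 24 h the medians were -0.13 and 0.10, also at percentiles 0 and 100, and at 3 h all 4 medians lay between 0.00 and 0.03. Retinoid genes had medians of 0.29 and 0.35 in AML12 at 3 h and 24 h, both at percentile 100, and of 0.07 and 0.08 in the v-erbA line, at percentiles 97.4 and 97.0.

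**Figure D3:**
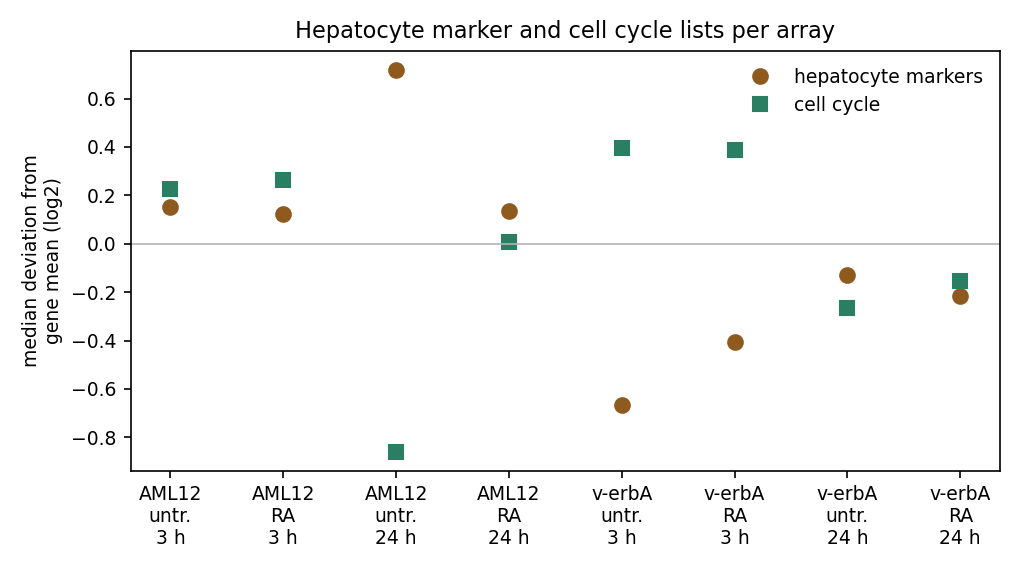
Median deviation from the gene mean over the 8 arrays (log2) for 25 hepatocyte markers (circles) and 28 cell cycle genes (squares) on each array. The untreated 24 h AML12 array has the highest hepatocyte value, 0.72, and the lowest cell cycle value, -0.86.

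In the fits, the RA response in AML12 had a median of -0.31 for hepatocyte markers (limma camera adjusted p = 3.96e-07; adjusted p = 0.702 with an estimated correlation) and of 0.40 for cell cycle genes (camera adjusted p = 2.12e-11; adjusted p = 0.702 with an estimated correlation), with 0 members of either past the threshold, also adjusted over the list alone. Without the untreated 24 h AML12 array these medians were -0.05 (camera adjusted p = 0.415) and 0.11 (camera adjusted p = 0.00737), in a fit that still uses the AML12 RA array at 24 h through the common time term. Between times the difference was -0.31 for hepatocyte markers (camera adjusted p = 3.66e-13; adjusted p = 0.576 with an estimated correlation), 12 of 25 being lower adjusted over the list alone and 0 over all genes. It was 0.47 for cell cycle genes (camera adjusted p = 6.32e-13; adjusted p = 0.576 with an estimated correlation). Without that array the differences between times were -0.19 (camera adjusted p = 5.31e-08) and 0.22 (camera adjusted p = 1.11e-08).

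Time in culture was the control comparison. Cell cycle genes were lower at 24 h, with 23 of 28 lower and 1 higher (25 and 1 adjusted over the list alone). The mitotic kinases Aurka (-1.12) and Plk1 (-0.95) and the cyclin Ccnb2 (-0.99) fell, and Ccne1 rose by 0.96. The median was -0.67 (limma camera adjusted p = 2.83e-09; adjusted p = 0.606 with an estimated correlation), and 24 of 27 other probe sets of these genes pointed the same way as the used ones, with a median of -0.53. Of 16 inflammatory and acute phase genes 11 rose and 2 fell (14 and 2 adjusted over the list alone), with Ccl20 at 1.86 and Icam1 at 0.97, a median of 0.41 (camera adjusted p = 8.49e-04; adjusted p = 0.606 with an estimated correlation), and 12 of 12 other probe sets in the same direction. Of 25 hepatocyte markers 13 rose and 1 fell (17 and 2 adjusted over the list alone), with Cps1 at 1.31 and Apoa2 at least 2.22-fold higher, a median of 0.46 (camera adjusted p = 0.00747; adjusted p = 0.681 with an estimated correlation), and a median of 0.08 over 12 other probe sets. Without the untreated 24 h AML12 array 10 rose and 1 fell, with a median of 0.30 (camera adjusted p = 0.0278). Of 17 cholesterol synthesis genes 9 rose and 0 fell (11 adjusted over the list alone), with a median of 0.21 (camera adjusted p = 0.0108; adjusted p = 0.606 with an estimated correlation).

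The largest single changes with time were followed by few other probe sets. Slc4a8, Adcy3, Dpysl5, Tmem158 and Krt78 lay below the pooled median on all 4 arrays of 24 h and were at least 93.2-fold, 29.5-fold, 9.90-fold, 7.07-fold and 5.52-fold lower there. Slc12a8, Cd8a, Mt3, Slc22a16 and Prr30 lay below it at 3 h and were at least 16.9-fold, 13.5-fold, 11.7-fold, 10.5-fold and 9.93-fold higher at 24 h. By the rule that chose them, all 10 had the same direction in 4 of 4 pairs and passed the threshold (limma adjusted p of at most 2.81e-05). Of the 7 other probe sets of these genes 4 pointed the same way. That of Dpysl5 went from 6.72 at 3 h to 4.72 at 24 h. Another of Adcy3 differed by 0.11 and another of Cd8a by 0.12, where the used ones differed by -5.54 and 4.47, and 1 of Tmem158 differed by 3.09 where the used one differed by -4.86. Of 94 genes with a second tested probe set whose used probe set differed at least 2-fold between times, the second one followed, in the same direction by over 0.5 log2 units, in 18 (19.1%, exact 95% binomial interval 11.8 to 28.6%). Between lines it followed in 118 of 146 (80.8%, 73.5 to 86.9%). Among all genes tested with limma, 2315 were higher and 1794 lower at 24 h, 669 by at least 2-fold. A second probe set was called in the same direction for 892 of the 1849 called genes that had one (48.2%, against 67.3% for v-erbA and 51.9% for RA over both lines). One was called in the opposite direction for 154 of the 1849, against 188 of 3224 for v-erbA and 0 of 79 for RA. With each array centred on its median the split was 1811 higher and 2232 lower, so 44.8% in place of 56.3% of the called genes were higher.

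**Figure D4:**
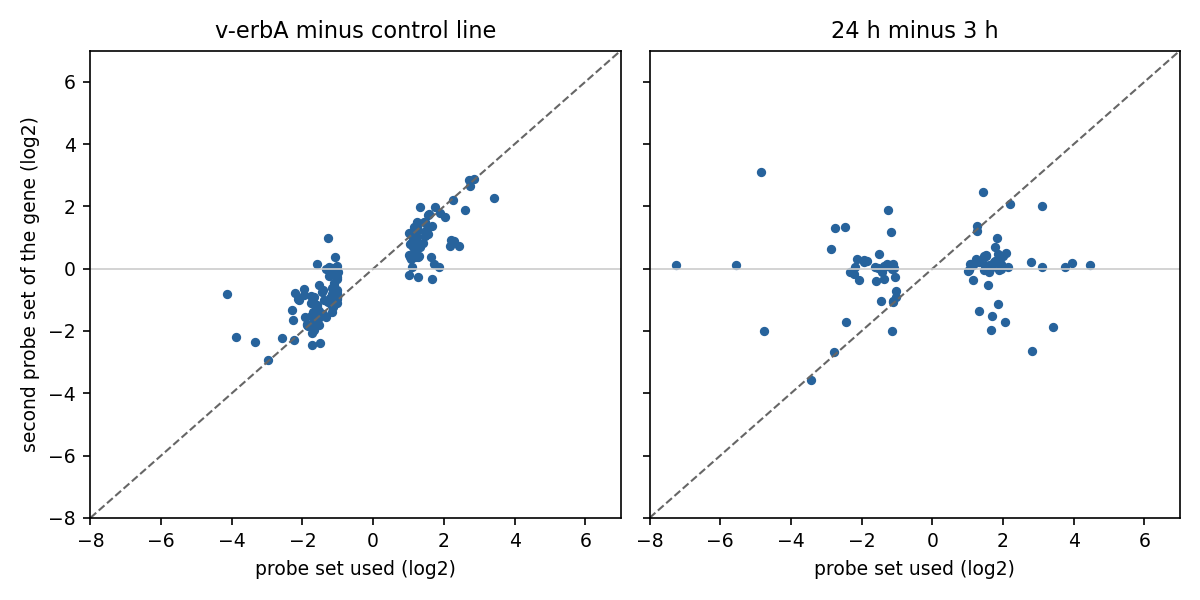
Log2 change of a second probe set (vertical) against that of the probe set used for the gene (horizontal), for genes whose used probe set differed at least 2-fold between lines (left, 146 genes) or times (right, 94 genes); the dashed line marks equal changes. Over all 5419 genes with a second tested probe set Pearson's correlation across genes was 0.714 for line and 0.180 for time, and Spearman's was 0.678 and 0.466.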

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

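The tests of second probe sets between times, of the 3 h arrays alone, of v-erbA as the source of a smaller RA response and of the shifts in the v-erbA line at 24 h were chosen only after the result was seen; those of dim signals, of the change of the 2 lists with time and of other splits of the arrays were chosen before.

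Differences of at least 2-fold between times rested largely on single probe sets. The second probe set followed in 18 of 94 genes changed at least 2-fold with time, which argues against a change of expression as the source of most of these changes, since between lines it followed in 80.8%. The 19.1% is consistent with arrays handled as separate sets at 3 h and 24 h, in production, hybridisation or computation, but no test gives the share that such handling would leave, and these steps cannot be told apart with 1 set per time. As many genes as the 4109 called for time were given by 2 of the 35 splits of the 8 arrays, the other being the split by line (4261). By the plain count of splits chance is therefore not excluded. Splits that follow no factor of the study gave 0, but they left the time difference in their spread, in whole or in part, which lowers their counts. A change of expression with time stays open for groups whose other probe sets followed, such as the cell cycle genes. It stays open for smaller changes too, but the second probe sets do not settle it. Over all called genes one was called the same way for 48.2% for time and 51.9% for RA, the latter from 79 genes. One was called the opposite way for 154 of 1849 genes for time, 188 of 3224 for v-erbA and 0 of 79 for RA.

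The RA response of the 143 called genes was smaller in the v-erbA line. These genes were called over both lines, which disfavours genes that respond in 1 line only and so limits the difference. A floor from dim signals is argued against as the whole source. The called genes that were brighter in the v-erbA line also had the smaller response there (-0.128, SE over 63 genes 0.0177, genes not being independent replicates). The difference was -0.0916 for called genes above their median signal and -0.147 for the others, where the AML12 response was 0.448 and 0.706. A part from dim signals is therefore not excluded. The untreated 24 h AML12 array is argued against as the whole source, since the 3 h arrays alone gave -0.143, against -0.119 over all arrays, but it may add to it, as the value was -0.0813 without that array. The difference was -0.0656 without the v-erbA RA array at 3 h and -0.173 without that at 24 h, the only omission with which the fry test, unadjusted, passed the threshold. An effect of v-erbA on the response stays open, as a hypothesis: the difference pointed the same way at both times, but limma's fry gave an adjusted p = 0.332 over the 6 fry tests, and v-erbA and clone cannot be separated in 1 transfected line.

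Hepatocyte markers differed in their RA response between lines by 0.31 and cell cycle genes by -0.32 (limma camera adjusted p = 1.82e-05 and 7.72e-10), and between times by -0.31 and 0.47, calls that were all lost with an estimated correlation (adjusted p = 0.638 between lines and 0.576 between times). From 3 h to 24 h the cell cycle median changed by -1.12 in untreated AML12, against -0.28, -0.75 and -0.62 in AML12 with RA, the untreated v-erbA line and the v-erbA line with RA, and the hepatocyte median by 0.88 against 0.06, 0.44 and 0.19. The untreated AML12 change lies outside the others by 0.37 for cell cycle genes, less than their range of 0.46, and by 0.44 for hepatocyte markers, more than their range of 0.38, so an array that stands apart and a response of AML12 to RA cannot be told apart with 1 array. Without it the differences between lines were 5.61e-05 and -0.06 (camera adjusted p = 0.999 and 0.275). A shift by RA in both lines is consistent with the v-erbA line at 24 h, which does not use that array and where the medians were -0.13 and 0.10, and it stays a hypothesis.

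Other differences of gene lists or genes stood out by their own test. Between lines the RA response differed by 0.29 for 4 macrophage markers, by -0.35 for 4 endothelial markers and by 0.054 for 17 cholesterol synthesis genes (limma camera adjusted p = 0.0461 for each; 0.638 with an estimated correlation). Without the untreated 24 h AML12 array these were 0.14, -0.31 and 0.13 (camera adjusted p = 0.507, 0.0111 and 0.0301). Between times it differed by -0.15 for 9 biliary and progenitor markers (camera adjusted p = 0.0263; 0.576 with an estimated correlation), and without that array the call was lost while the median stayed at -0.15 (camera adjusted p = 0.278). Sprr1a responded more at 24 h by 1.89. Rnase4 did so by 3.49 as measured against dim untreated signals at 24 h, and by 1.95 with dim signals set to the filter level, a setting in which neither gene passed. Neither had another tested probe set, so a difference between the 3 h and 24 h arrays in how these probe sets measured is not excluded.

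For the genes called between the lines, 1 of 35 splits of the 8 arrays gave as many, the real one with 6413. The highest other, by time, gave 1167. The other splits left the line difference in their spread, in whole or in part, which lowers their counts. The count therefore follows line, but these splits cannot exclude a chance difference between cultures or clones. For RA over both lines 3 of 35 splits gave as many as the real 143, the larger ones being the splits by line (6209) and by time, which point to the other factors of the study, and the highest among splits that follow none gave 18; by the plain count of splits chance is not excluded.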

How the results depend on the processing

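The fits to the 3 h or 24 h arrays alone, the model with line by time, the counts with a second probe set, the lists without the untreated 24 h AML12 array, dim signals set to the filter level and all settings for the line difference of the RA response were chosen after seeing the data; the others were planned. For genes named in the text, 1267 alternative values kept direction and side of the threshold, 178 lost the call, 26 gained it and 2 reversed; for gene lists these were 280, 27, 6 and 2. The reversals were Tmem158 between times with no offset, 4.07, where another of its probe sets is used; Zfr2 in the line difference of the RA response with dim signals set to the filter level, 0.063, which follows from that setting; macrophage markers in the line difference of the RA response with the mean of all probe sets, -0.026 (the cause was not tested); and hepatocyte markers there without the untreated 24 h AML12 array, where only camera's direction turned and the median shrank to 5.61e-05 (camera adjusted p = 0.999). With all 2-way interactions, which leave 1 residual degree of freedom, RA over both lines gave 628 genes, RA in AML12 596, RA in the v-erbA line 125, the difference between lines 3 and that between times 121. Without the trend these were 17 for RA over both lines, 2 in AML12 and 0 for the difference between times. RA in the v-erbA line gave 4 genes with median centring, 1 with no offset, 4 with no dim filter and 3 with a filter on all 8 arrays. The difference between times gave 1 gene with quantile normalization, with a double offset and with a filter on all 8 arrays, and RA in AML12 gave 18 with the mean of all probe sets. With dim signals set to the filter level the difference between times gave 0 genes and the 2-fold ratios in the v-erbA line at 3 h gave 4. The causes were not tested. The 3 h arrays alone gave 506 genes for RA, from 1 residual degree of freedom, and the 24 h arrays alone 152 (68 higher, 84 lower), of which 66 were among the 143. Counting genes with a second probe set called the same way, which fewer genes have, gave 2169 for v-erbA, 41 for RA and 892 for time. At a fold of at least 1.5 the pairs of arrays gave 166 and 576 genes in AML12 and 71 and 142 in the v-erbA line at 3 h and 24 h. In AML12 at 3 h no offset gave 37 and no dim filter 65; in the v-erbA line no dim filter gave 34 at 3 h and 41 at 24 h, and at 24 h no offset gave 34 and a double offset 14. Leaving out each array in turn gave 5474 to 6277 genes for v-erbA, 36 to 143 for RA over both lines, 3014 to 3867 for time, 5 to 246 for RA in AML12, 0 to 3 for RA in the v-erbA line, 0 to 2 for the difference between lines and 0 to 102 for that between times. For the line difference of the RA response of the called genes it gave -0.173 to -0.0656, and other settings left it without a call. With matched pairs as a block the v-erbA count was 6528, and no replicate numbers pair other arrays. Genes near the 19.9-unit offset have compressed folds.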

Other observations

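Over all 11997 genes, Pearson's correlation across genes of the RA response was 0.245 between AML12 and the v-erbA line at 3 h and 0.368 at 24 h, against 0.150 between 3 h and 24 h within AML12 and 0.144 within the v-erbA line. Between AML12 at 3 h and the v-erbA line at 24 h it was 0.230, close to the same-time value at 3 h, and between AML12 at 24 h and the v-erbA line at 3 h it was 0.162. The 4 responses share no array, and genes are not independent replicates. No test was made of these differences.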
